A study of Mus musculus with 33 samples.

How the data were processed

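The samples were 33 libraries of lymph node B cell lymphomas from Eµ-myc mice, 26 of them p53 immunoprecipitates with the CM5p antibody and 7 input libraries. Per the labels' protocols, lymph nodes were pressed to single cells without further purification and chromatin was sonicated to fragments averaging 250 bp. The 26 immunoprecipitates each came with a peak list, and the inputs were not used here. Per the submitters' processing notes, the authors used BWA 0.6.2 and SAMtools and the mouse build mm9. The peak caller, its threshold and the use of the inputs are not given in the sources used here.

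The deposited lists hold 3 columns, chromosome, start and end of each peak in base pairs, without a score, a height or a p-value, so that the authors' deposited values allow only position and width to be compared. Each list belongs to 1 library and was used as deposited, with no region removed here as repeat or high background. Coordinates are mm9 and are printed counted from 1. The annotation at hand was of another build, GRCm38, so regions are given by position without gene names, and nearby genes, distance to transcription start sites and the p53 motif were not analysed here. Gene lists fixed before the data were examined were therefore not used.

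Groups were taken from the sample titles: EtOH (1 volume per 1000) and 100 nM OHT for 2 h in KI tumours 1 to 4, and untreated, water, DMSO (0.5 volumes per 1000), 5 µM (+)-Nutlin, 5 µM (-)-Nutlin and 1 µM doxorubicin for 3 h in Arf tumours 5 to 7. The tumour number in the titles marks cells of the same tumour and so pairs the samples. As a check in Arf tumours, control and (+)-Nutlin lists of the same tumour had a mean Jaccard index of 0.562 and those of different tumours 0.254. Tumour 5 differs from the others in peak width, and between tumours 6 and 7 alone the means were 0.558 and 0.436. KI tumours were not checked in this way. KI and Arf tumours differ in genotype, time and treatment together.

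The lists fall into 2 kinds. In 12 lists the smallest peak was 52 to 54 bp, the median width was 68 to 111 bp, and 11.4% to 39.6% of peaks lay within 500 bp of the next. In the other 14 lists the smallest peak was 278 to 391 bp, the median was 417 to 552 bp, and 0.48% to 2.09% lay that close. The narrow kind comprised all EtOH lists and the untreated, water, DMSO and (+)-Nutlin lists of tumours 6 and 7. All lists of tumour 5 were of the wide kind, as were all OHT, doxorubicin and (-)-Nutlin lists. Comparisons of treated with control lists therefore cross the kinds except in tumour 5, while comparisons among control and (+)-Nutlin lists stay within one kind in each tumour. Several short peaks close together count as several peaks where a wide list would hold 1, so covered length and merged peaks were also compared.

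Numbers of peaks were compared on the log2 scale by two-sided exact permutation tests over libraries, and paired by exact sign changes within tumours. The 95% intervals of folds come from the paired log2 differences, on the assumption that these are normal. Peaks of the libraries compared were merged into regions where they shared at least 1 bp. A region was gained when every list of the first group and no list of the second had a peak in it, and lost in the opposite case. Fisher's exact test per region was adjusted by the Benjamini-Hochberg method over all regions, with a threshold of 0.05. Doxorubicin and (-)-Nutlin lists were also joined and tested against the other 12 Arf lists, with permutation within tumours as the paired form. Overlap of gained sets was set against 1000 circular shifts along each chromosome, and the share of control peaks under treated peaks against 100 shifts, which gave at most 0.54%.

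By a rule fixed before the data were examined, the named regions were taken from the 10 best gained regions of each of the 3 main comparisons and the 5 best regions present in every control list, ranked by mean percentile of peak width within each list. Width stood in for the score that the lists lack. Regions behind counts of 5 or fewer were named after their values were seen. The 9 regions in every list were likewise singled out afterwards.

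Alternatives fixed beforehand were covered base pairs, peaks of at least 457 bp (the median width over all peaks), merging of peaks within 500 bp, the tumour as a block, peaks of 200 bp around the midpoint, a merge gap of 200 bp, 1 list of each group allowed to differ, lists cut to their widest peaks, as many as in the shortest list of the first (treated) group, with shorter lists kept whole, an adjusted p under 0.01, an overlap of 50% of the shorter region and leaving out each tumour. Added after seeing the data were tumour 5 alone and the same settings for the shares of control peaks, the core regions and the Jaccard index of control lists, and the 11821 regions in at least 3 lists as a second universe for the overlap of gained sets. The code was tested on simulated lists. With detection of 100%, all 200 simulated gained regions were recovered for OHT against EtOH among 4600 regions. With detection of 90% per list 64.0% were recovered, against 65.6% by calculation, and Fisher's exact test for the 6 against 12 libraries recovered 89.5% of 200 among 7600 regions. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.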

Results

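Binding of p53, the transcription factor encoded by Trp53, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in B cell lymphomas of Eµ-myc mice, which express the Myc oncogene in B cells. The question was where p53 binds once its function is restored or activated in these tumours. One set of 4 lymphomas, tumours 1 to 4, carried a knock-in (KI) allele of Trp53 over a deleted one. Cells of each KI tumour were given 100 nM OHT (4-hydroxytamoxifen) or its solvent ethanol (EtOH) for 2 h. A second set of 3 lymphomas, tumours 5 to 7, lacked Arf, an inhibitor of Mdm2, and kept both wild-type Trp53 alleles. Each of these Arf tumours was sampled untreated and after 3 h with water, DMSO, 5 µM (+)-Nutlin, 5 µM (-)-Nutlin or 1 µM doxorubicin, a DNA-damaging drug. The Nutlins are mirror-image forms of one molecule, of which the (-) form blocks the binding of p53 by Mdm2. The 26 ChIP libraries gave 26 peak lists with 102916 peaks in all, which merged into 18927 regions. The lists held between 116 and 11346 peaks. Read depth per library is unknown here, so the number of peaks reflects both binding and sensitivity.

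Restoring p53 function with OHT widened the set of called p53 sites in every KI tumour. EtOH lists held 353 ± 280 peaks (SD, n = 4) and OHT lists 6880 ± 3509 (SD, n = 4), a ratio of 22.3 between geometric means. OHT exceeded EtOH 35.4-fold in tumour 1, 19.3-fold in tumour 2, 13.6-fold in tumour 3 and 26.5-fold in tumour 4. Of the peaks called in EtOH cells, 91.3% ± 5.8 (SD, n = 4) lay under an OHT peak of the same tumour. EtOH peaks of tumours 1 and 2 lay more often under OHT peaks of tumour 3 (91.4% and 95.2%) than of their own (89.7% and 83.9%). Those of tumours 3 and 4 lay most often under their own. The log2 ratio of peak numbers was 4.48, with p = 0.0286 in a two-sided exact permutation test, the smallest value that 4 against 4 libraries allow. With tumours paired the exact p was 0.125, again the smallest possible, and the paired 95% interval ran from 11.6-fold to 42.9-fold. All 4 EtOH lists consisted of narrow peaks, with medians of 68 to 105.5 bp, and all 4 OHT lists of wide peaks, with medians of 443 to 481 bp, so that the kind of list changes together with treatment in KI tumours. Merging peaks within 500 bp, which joins sites split into several narrow peaks, gave a log2 ratio of 4.76 with an exact permutation p of 0.0286, and folds of 51.9, 21.3, 15.8 and 30.6 in tumours 1 to 4.

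Some sites were gained in every KI tumour with OHT. Of 12799 regions called in KI tumours, 1191 had a peak in all 4 OHT lists and in no EtOH list. The opposite count was 0, but just 11 regions were called in all 4 EtOH lists, so it could not have been high. Ranked by width within the lists, the first gained region lay on chromosome 8 from 23543549 to 23545850 (mm9 throughout), with peaks of 1315 to 2302 bp in the 4 OHT lists. Next came regions on chromosome 5 from 136645987 to 136648197 and from 92390449 to 92392507, and on chromosome 1 from 173480352 to 173481887. Each of these regions was called in all 10 lists of OHT, doxorubicin or (-)-Nutlin. The regions on chromosomes 8 and 1 were also called in all 12 lists of untreated, solvent-treated or (+)-Nutlin-treated Arf tumours, although in no EtOH list of a KI tumour. A region on chromosome 4 from 140239509 to 140240901 was called in all 10 OHT, doxorubicin and (-)-Nutlin lists and in none of the 16 others. Another, on chromosome 12 from 101590195 to 101591757, was called in 4 of 4 OHT lists, 3 of 3 doxorubicin lists and 1 of 3 (-)-Nutlin lists, and in no other list. Fisher's exact test per region with Benjamini-Hochberg adjustment called 0 regions, with a lowest adjusted p of 0.307, although 1191 had an unadjusted p of 0.0286. The count became 2201 without tumour 1 and 2030 without tumour 2, 3791 when 1 list of each group could differ, 485 among peaks at or above the median width of all peaks, and 553 when the OHT lists were cut to the length of the shortest of them, with the shorter EtOH lists kept whole.

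**Figure D1:**
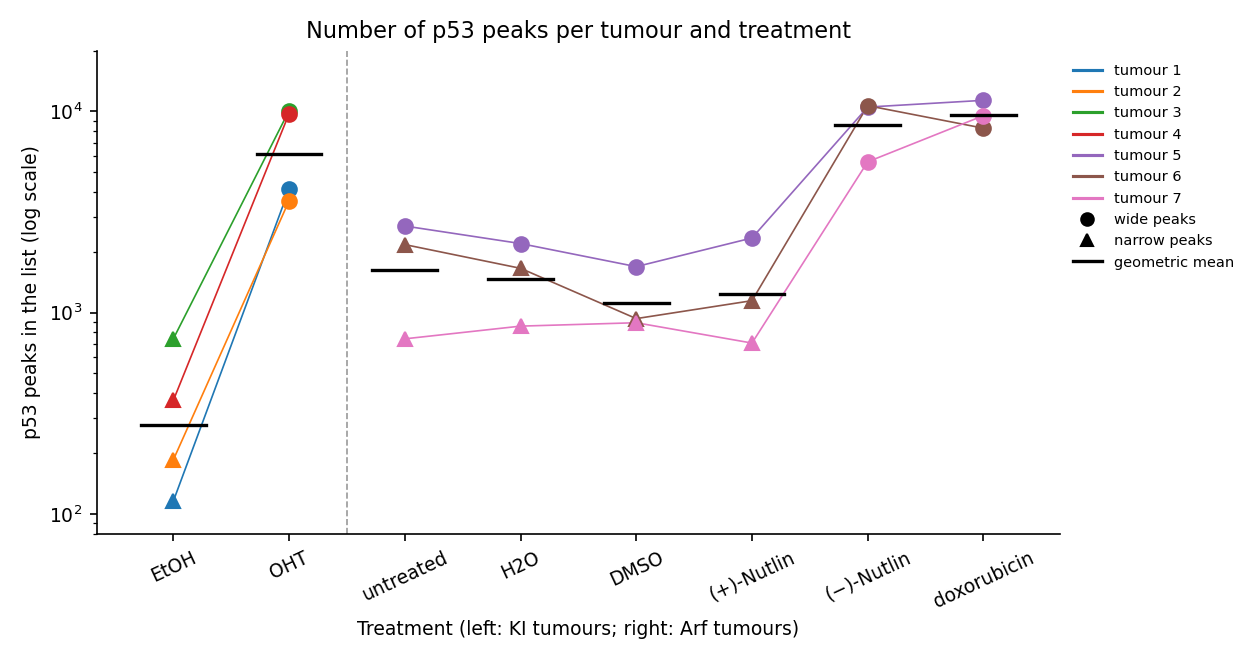
Number of p53 peaks per list (vertical log axis) by treatment (horizontal axis), with lines joining the lists of one tumour, circles for lists of wide peaks, triangles for lists of narrow peaks and black bars for geometric means. OHT lists hold 3597 to 10084 peaks against 116 to 742 with EtOH, and (+)-Nutlin lists lie near the DMSO lists.

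Doxorubicin raised the number of peaks in each of the 3 Arf tumours. Lists from water-treated cells held 1575 ± 678 peaks (SD, n = 3) and doxorubicin lists 9706 ± 1556 (SD, n = 3), a 6.57-fold difference between geometric means. The increase was 5.14-fold in tumour 5, 4.96-fold in tumour 6 and 11.1-fold in tumour 7. Nearly all sites of water-treated cells persisted, since 95.8% ± 2.4 (SD, n = 3) of their peaks lay under a doxorubicin peak of the same tumour. The exact permutation p was 0.1, the smallest that 3 against 3 libraries allow, with a paired 95% interval from 2.12-fold to 20.3-fold. Both lists of tumour 5 were of wide peaks.

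Doxorubicin-gained regions, called in all 3 doxorubicin lists and in no water list, numbered 2728 of 15038. Of 437 regions called in all 3 water lists, 0 were lost. The first by width lay on chromosome 13 from 30805898 to 30807601, and was called in 9 of the 10 OHT, doxorubicin and (-)-Nutlin lists and in none of the 16 others. A region on chromosome 7 from 53861586 to 53863340 showed the same totals. On chromosome 8, from 101370984 to 101372540, a region was called in all 3 doxorubicin and all 3 (-)-Nutlin lists but in none of the OHT lists. On chromosome 16, from 76642863 to 76644387, another was called in 3 doxorubicin lists, 2 (-)-Nutlin lists and no OHT list. The region on chromosome 11 from 40546917 to 40548201 was called in all 10 OHT, doxorubicin and (-)-Nutlin lists and in 2 control lists. No region reached significance alone, because Fisher's exact test at 3 against 3 cannot give p under 0.1, and 0 regions had an unadjusted p under 0.05. The count became 5705 without tumour 6 and 4602 without tumour 5, 8195 when 1 list of each group could differ, and 1453 among the wider peaks.

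The Nutlins differed by their stereochemistry alone, at the same dose and time. (-)-Nutlin lists held 8931 ± 2872 peaks (SD, n = 3), DMSO lists 1174 ± 451 (SD, n = 3) and (+)-Nutlin lists 1402 ± 851 (SD, n = 3). Between geometric means, (-)-Nutlin exceeded DMSO 7.64-fold and (+)-Nutlin 6.91-fold. The ratio of (-)-Nutlin to (+)-Nutlin was 4.47 in tumour 5, 9.30 in tumour 6 and 7.94 in tumour 7, with a paired 95% interval from 2.65 to 18.02. (+)-Nutlin against DMSO gave a ratio of 1.11, and the values of 1.39, 1.23 and 0.79 in tumours 5, 6 and 7 lay on both sides of equality. The exact permutation p was 0.1 for (-)-Nutlin against DMSO and against (+)-Nutlin, the smallest possible, and 0.8 for (+)-Nutlin against DMSO. For the last comparison the paired 95% interval, from 0.53-fold to 2.30-fold, leaves room for a difference in either direction, and without tumour 5 the log2 ratio was -0.020 instead of 0.14. In tumour 5, where all lists were of wide peaks, (-)-Nutlin exceeded DMSO 6.20-fold.

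Site by site the contrast was of the same kind. (-)-Nutlin gained 3532 regions over DMSO, of 12661, and 2988 over (+)-Nutlin, of 12660. (+)-Nutlin gained 1 region over DMSO, of 2901, and lost 0. That region lay on chromosome 7 from 87171548 to 87171954, had a peak in 7 of the 26 lists, and was singled out after its values were seen. The peaks of DMSO-treated cells lay under a (-)-Nutlin peak of their tumour in 97.1% ± 1.7 (SD, n = 3) of cases, and those of (+)-Nutlin-treated cells in 97.0% ± 0.9 (SD, n = 3). The first (-)-Nutlin-gained region by width lay on chromosome 17 from 27691990 to 27693799, with peaks of 1686 to 1783 bp, and was called in 8 of the 10 OHT, doxorubicin and (-)-Nutlin lists. Another on chromosome 7 from 3644275 to 3646123 was called in 8 of these lists and in none of the 16 others. Regions on chromosome 1 from 180248306 to 180249525 and on chromosome 19 from 8893499 to 8894793 were called in all 10 and in 4 control lists each. The exception to gain was a region on chromosome 2, from 98502226 to 98503234, called in every (+)-Nutlin list and in no (-)-Nutlin list. A slightly shorter form of it, from 98502250 to 98502955, was likewise lost against DMSO. Whether this region is a p53 site was not tested, as no region was removed here as repeat or high background. Fisher's exact test had 0 regions with an unadjusted p under 0.05 in any of these comparisons, which 3 against 3 libraries cannot give. Without tumour 7 the gain over DMSO became 6872 regions and that over (+)-Nutlin 6215, and it fell to 1547 and 1330 among the wider peaks. The gain of (+)-Nutlin over DMSO ranged from 0 to 48 regions under other merging rules or with 1 tumour left out, was 15 against 26 lost without tumour 5, and was 187 against 107 lost when 1 list of each group could differ.

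Doxorubicin and (-)-Nutlin, which activate p53 by different routes, were compared in the same 3 tumours. The ratio of peak numbers between geometric means was 1.12, with an exact permutation p of 0.8 and a paired 95% interval from 0.42-fold to 2.99-fold. In covered length, however, every doxorubicin list exceeded every (-)-Nutlin list, with 5.98 ± 0.64 Mb (SD, n = 3) against 4.55 ± 1.04 Mb (SD, n = 3). The log2 ratio of covered length was 0.42 and that of the number of wider peaks 0.51, each with an exact permutation p of 0.1, the smallest possible. By number of peaks, doxorubicin exceeded (-)-Nutlin 1.70-fold in tumour 7 and 1.08-fold in tumour 5, and reached 0.77 of it in tumour 6. Of 17070 regions, 3206 were called in all 6 lists, 446 in every doxorubicin list and no (-)-Nutlin list, and 36 in every (-)-Nutlin list and no doxorubicin list. The mean Jaccard index, the shared share of covered base pairs, was 0.445 within a tumour and 0.414 between tumours, a difference that was not detectable here (exact permutation p = 0.667, smallest possible 0.167). Without tumour 7 the log2 ratio of peak numbers was -0.13 instead of 0.17, and the balance of 446 doxorubicin-only to 36 (-)-Nutlin-only regions turned to 548 against 637. It was 1570 against 350 without tumour 5, 838 against 55 without tumour 6, and 2362 against 2113 when 1 list of each group could differ. Fisher's exact test had 0 regions with an unadjusted p under 0.05 in this comparison.

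Taking doxorubicin and (-)-Nutlin lists together against the other 12 lists of Arf tumours gave enough libraries for a test per region. Peak numbers differed 6.72-fold between geometric means, with p = 5.39e-05 in an exact permutation test over the 6 and 12 libraries and 0.000296 when labels were permuted within tumours, each the smallest value possible. Of 17143 regions, 5932 were called more often in the 6 activated lists and 3 less often, by Fisher's exact test with Benjamini-Hochberg adjustment. The 3 regions called less often lay on chromosome 2 from 98502226 to 98503234, on chromosome 6 from 3151460 to 3151549 and on chromosome 8 from 124364677 to 124364733. They had a peak in 0 activated lists and in 10, 8 and 8 of the 12 others, with adjusted p of 0.00875, 0.037 and 0.037 by Fisher's exact test. The regions on chromosomes 6 and 8 are shorter than 278 bp, the smallest peak of any wide list. All lists with a peak there were therefore narrow lists of tumours 6 and 7. For these regions the kind of list cannot be told apart from an effect of treatment. The 5932 regions called more often share this limit in part. All 6 activated lists were wide, while of the 12 others only those of tumour 5 were. A region called in wide lists alone could thus be among them, also when labels are permuted within tumours. How many follow the kind of list was not tested. Lists of one tumour are not independent, and all 5932 regions were also called when labels were permuted within tumours. The count became 1294 without tumour 7, 1720 without tumour 5, 2011 without tumour 6, 3324 among the wider peaks, 1848 with the activated lists cut to the shortest of them, and 2954 at an adjusted p under 0.01.

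No effect of a solvent on the number of peaks was detected in Arf tumours. Water gave 0.90 of the untreated number of peaks between geometric means, with a paired 95% interval from 0.52 to 1.56 and an exact permutation p of 0.8. DMSO gave 0.69 of it, with an interval from 0.19 to 2.51 and an exact permutation p of 0.4. Water gained 1 region over untreated cells, on chromosome 11 from 102269734 to 102270132, and lost 1, on chromosome 15 from 98748459 to 98748808. DMSO gained 1, on chromosome 7 from 28835032 to 28835386, and lost 4. The lost ones were the same region on chromosome 15 and regions on chromosome 12 from 45054592 to 45054932, chromosome 2 from 127951397 to 127951821 and chromosome 5 from 82062836 to 82063399. These few regions were named after their values were seen. Among the untreated, water, DMSO and (+)-Nutlin lists, lists of one tumour overlapped more than lists of different tumours, with mean Jaccard indices of 0.562 and 0.254 and an exact permutation p of 0.00463, the smallest possible. Tumour 5 differs from tumours 6 and 7 in peak width, and between tumours 6 and 7 alone the indices were 0.558 and 0.436, with an exact p of 0.125, again the smallest possible. Single pairs could go the other way. The DMSO list of tumour 6 had an index of 0.506 with untreated tumour 7 and 0.410 with untreated tumour 6.

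Untreated Arf tumours were set beside KI tumours under EtOH, the unactivated state of each set. The ratio of geometric mean peak numbers was 5.90, with an exact permutation p of 0.0857 for 3 against 4 libraries, and untreated tumour 7 had 742 peaks, as many as EtOH tumour 3. A set of 336 of 3639 regions was called in all 3 untreated Arf lists and in no EtOH list. These 336 regions had a peak in 95.2%, 71.7%, 78.3% and 51.8% of cases in the OHT lists of tumours 1, 2, 3 and 4. All of them had a peak in each doxorubicin and each (-)-Nutlin list. The comparison crosses genotype, time and solvent, and for tumour 5 also the kind of list, since its peaks are wide and all EtOH peaks narrow. Fisher's exact test with Benjamini-Hochberg adjustment called 0 regions, with 336 at an unadjusted p under 0.05 and a lowest adjusted p of 0.309. Over covered base pairs the log2 ratio was 3.92 instead of 2.56, with an exact permutation p of 0.0286, and among the wider peaks it was 6.37 with the same p. Both settings weigh against the narrow EtOH peaks, so these values also reflect the kind of list.

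Sites gained by restoring p53 in KI tumours mostly also had a peak in Arf lists after activation. The 1191 OHT-gained regions had a peak in 87.5% ± 10.7 (SD, n = 3) of cases in doxorubicin lists and 89.8% ± 10.9 (SD, n = 3) in (-)-Nutlin lists. In untreated Arf lists the share was 29.3% ± 14.0 (SD, n = 3), and in DMSO lists 21.3% ± 6.5 (SD, n = 3). These shares were not corrected for list length. Doxorubicin and (-)-Nutlin lists held 5617 to 11346 peaks and the other Arf lists 707 to 2696, and a longer list can hold more of any set. The contrast therefore does not show that these sites are particular to the activated state. In the reverse direction, doxorubicin-gained regions had a peak in 46.0% ± 11.9 (SD, n = 4) of cases in OHT lists, and (-)-Nutlin-gained regions in 63.7% ± 28.9 (SD, n = 4). Between the gained sets themselves, 399 OHT-gained regions, or 33.5%, met a doxorubicin-gained region, and 552, or 46.3%, a (-)-Nutlin-gained one. Of the doxorubicin-gained regions 1206, or 44.2%, met a (-)-Nutlin-gained region. Circular shifts along the chromosomes gave means of 2.09, 2.59 and 5.52 such regions, with a one-sided permutation p of 0.001 each, the smallest that 1000 shifts can give. Drawing both sets independently from the 18927 regions would give 171, 222 and 508 shared regions, and the observed numbers were 2.33, 2.50 and 2.37 times as high. Many of these regions could not be gained, and among the 11821 called in at least 3 lists the ratios were 1.45, 1.56 and 1.48, a setting chosen after seeing the data.

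**Figure D2:**
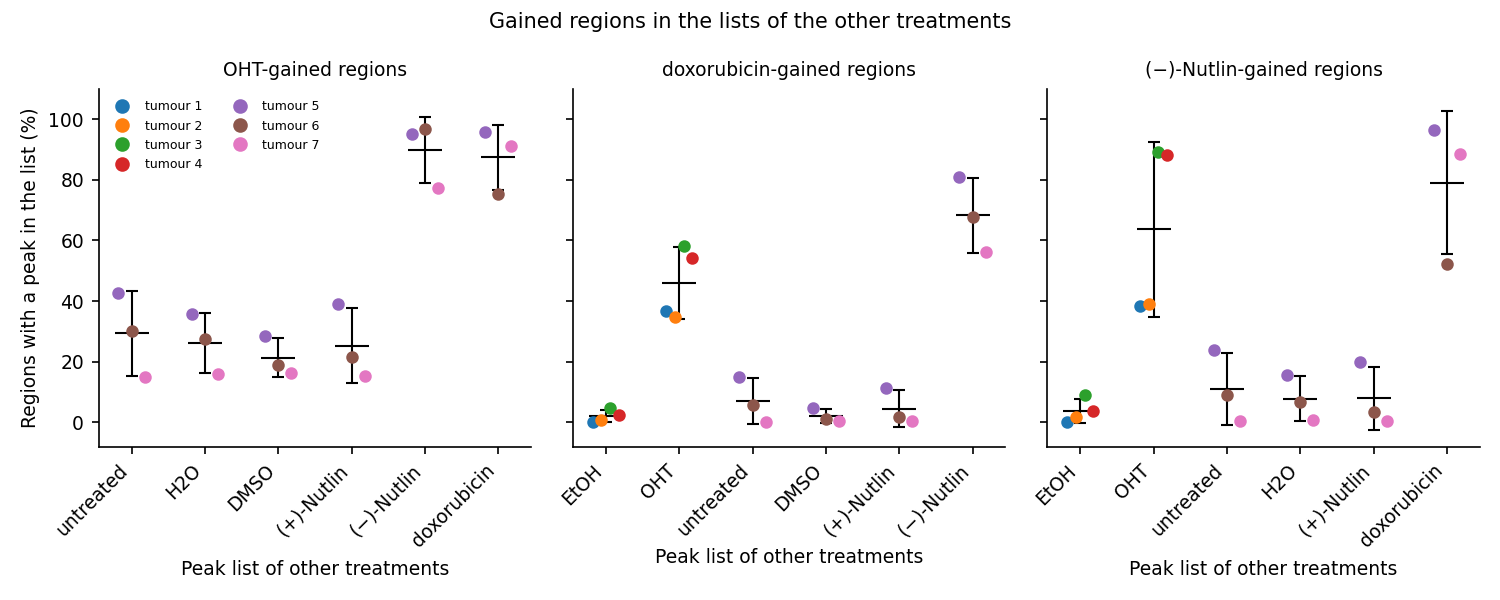
Share of gained regions with a peak in each list of the other treatments (vertical axis, percent), by treatment (horizontal axis), for regions gained with OHT, doxorubicin and (-)-Nutlin; points are single lists coloured by tumour, and bars give mean ± SD. OHT-gained regions stand at 87.5% in doxorubicin and 89.8% in (-)-Nutlin lists on average, against 21.3% to 29.3% in control lists of Arf tumours. The control lists are shorter, and the shares are not corrected for list length.

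A core of 1091 regions, 5.76% of the 18927, was called in all 10 lists of OHT, doxorubicin and (-)-Nutlin. Of this core 82.9% had a peak in at least 1 control or (+)-Nutlin list of Arf tumours, 31.6% in at least 1 EtOH list, and 163 regions in none of the 16 lists. At the other end 4850 regions, 25.6%, were called in 1 list alone, and 87 in no OHT, doxorubicin or (-)-Nutlin list. Regions called in every list of the series numbered 9. They included a region on chromosome 1 from 156902108 to 156907064, on chromosome 7 from 16892674 to 16895642, on chromosome 8 from 4610060 to 4613817 and on chromosome 19 from 44326969 to 44329957. The first of these ranked highest by width among regions present in all control lists in each of the 3 main comparisons, with a mean width percentile of 99.6 in EtOH, 99.9 in water and 99.8 in DMSO lists. A further region of all water and all DMSO lists, on chromosome 7 around 71471315 to 71473882, was called in 10 of 10 OHT, doxorubicin and (-)-Nutlin lists and in 2 of 4 EtOH lists.

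**Figure D3:**
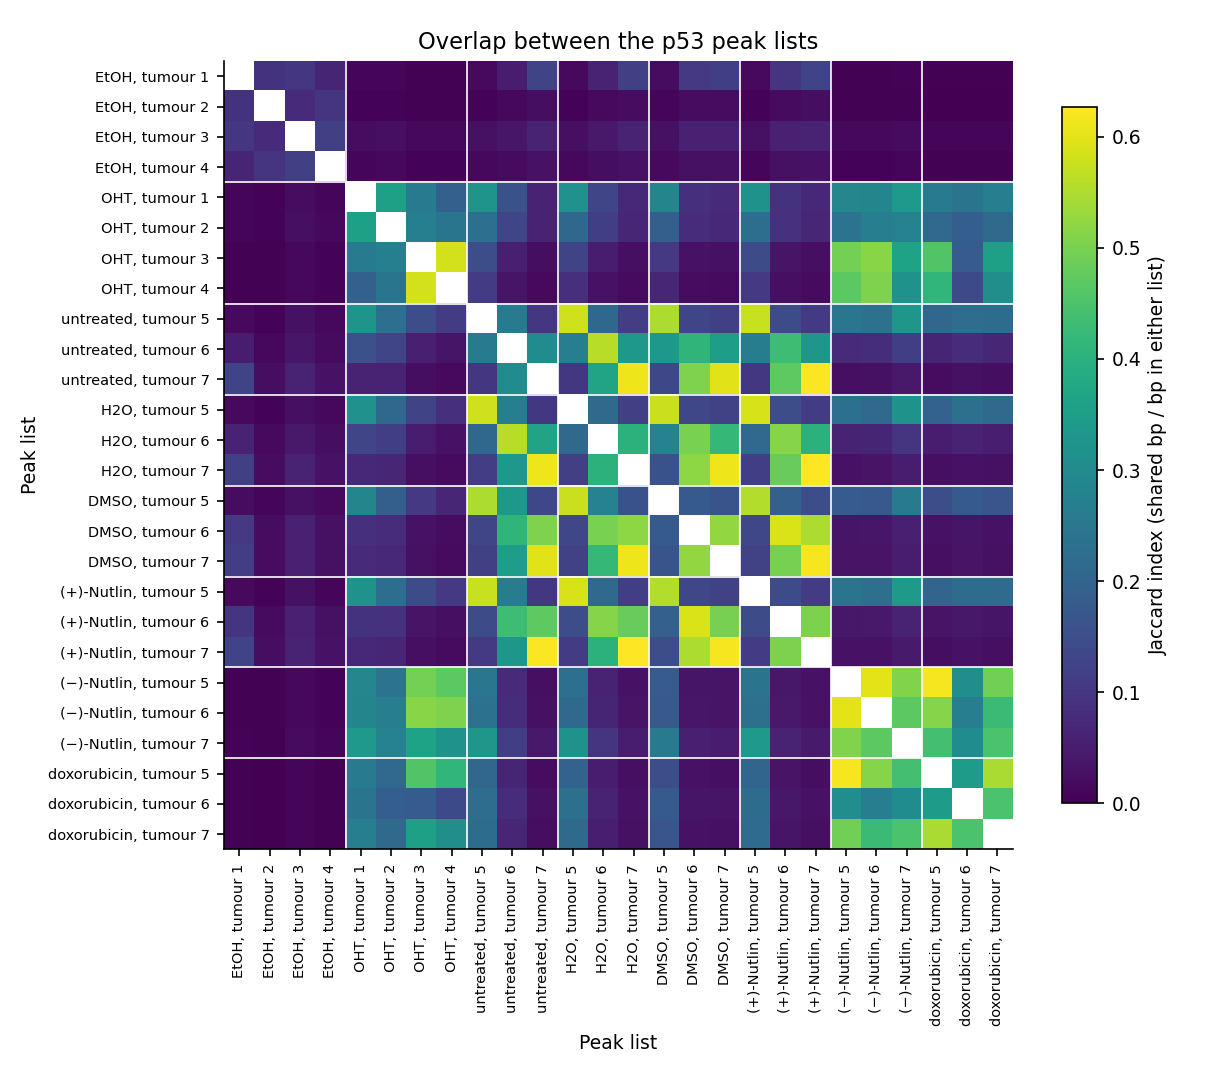
Jaccard index (colour scale, shared base pairs over base pairs in either list) for each pair of the 26 peak lists, ordered by treatment on both axes, with the diagonal left blank. The index of EtOH lists with any other list is at most 0.129. Their covered length of 0.015 to 0.069 Mb limits it against lists that cover more. Between EtOH lists it is 0.066 to 0.118, and lowest for tumours 1 and 4, which cover 0.023 and 0.033 Mb. Covered length does not account for that low value. Control lists of one tumour overlap more on average than those of different tumours, and the index between 2 lists reaches 0.627 at most.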

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

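Tumour 5 alone was an alternative chosen after seeing the data, as were all alternatives for the shares of control peaks, the core regions and the Jaccard index of control lists. Of 214 alternatives over 27 results, 160 kept direction and side of the threshold, or stayed within 1.5 times a count or within the spread. Read depth was not analysed here, and the lists give no score, so a stricter threshold was set by width alone. That setting also removes most narrow peaks. Gene lists, the p53 motif and the position of regions relative to genes were planned but not run, for lack of an annotation and genome of build mm9.

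For the number of peaks, the log2 ratio of OHT over EtOH of 4.48 had p = 0.0286 by exact permutation, and 0.125 with tumours paired as a block, and it lay between 4.26 and 4.72 without 1 tumour, where p was 0.1. Both p-values are the smallest these designs allow, so fewer arrangements account for the change. Pairing kept the call for the 6 activated against 12 other Arf lists. Comparisons between single treatments in Arf tumours could give no call with or without pairing. Untreated Arf against EtOH KI passed the threshold over covered base pairs, at 3.92, and among the wider peaks, at 6.37. Both settings weigh against narrow peaks, the kind of all EtOH lists. The 6 activated against 12 other Arf lists gave 2.31 in tumour 5 alone, without a test, against 2.75. Directions without a call reversed in 3 cases: (+)-Nutlin over DMSO was -0.020 without tumour 5 (0.38 at most without another), doxorubicin over (-)-Nutlin was -0.13 without tumour 7 (0.44 at most), and water over untreated was 0.090 among the wider peaks. The cause of these changes was not tested. Doxorubicin over (-)-Nutlin was 0.42 over covered base pairs and 0.51 among the wider peaks, with an exact permutation p of 0.1 each, the smallest possible.

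Counts of gained regions moved with recurrence and with list cutting. Among the wider peaks they were 485 for OHT, 1453 for doxorubicin, 1547 for (-)-Nutlin over DMSO, 1330 over (+)-Nutlin and 0 for (+)-Nutlin over DMSO. With 1 list of each group free to differ they were 3791, 8195, 8268, 8193 and 187, and 2362 for doxorubicin over (-)-Nutlin. With treated lists cut to the shortest of them, and still longer than control lists, they were 553 for OHT, 1920 for (-)-Nutlin over DMSO and 1511 over (+)-Nutlin. (+)-Nutlin over DMSO gave 0 with 200 bp peaks and with a merge gap of 200 bp. Without 1 tumour the ranges were 1370 to 2201 for OHT, 3139 to 5705 for doxorubicin, 3880 to 6872 for (-)-Nutlin over DMSO, 3350 to 6215 over (+)-Nutlin, 15 to 48 for (+)-Nutlin over DMSO and 548 to 1570 for doxorubicin over (-)-Nutlin. The opposite count of the last comparison, 36, was 350, 55 and 637 without tumours 5, 6 and 7, and 2113 with 1 list free to differ, and without tumour 7 it exceeded the 548. Fewer lists make the criterion easier by construction.

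The 5932 regions called by Fisher's exact test in the 6 against 12 lists became 3324 among the wider peaks, 2954 at an adjusted p under 0.01, 1848 with activated lists cut to the shortest and 1294 to 2011 without 1 tumour, where fewer libraries enter. With the tumour as a block they were 7725. The overlaps of gained sets kept a permutation p of 0.001, the smallest 1000 shifts can give, under every alternative run, with shares of 25.8% to 70.1% for OHT with doxorubicin, 39.7% to 79.2% for OHT with (-)-Nutlin and 29.5% to 70.6% for doxorubicin with (-)-Nutlin. Cutting peaks to 200 bp lowered the shares of control peaks under treated peaks to between 67.1% and 79.1%, and the core fell to 298 regions among the wider peaks. For the Jaccard index of control lists, the difference between same and other tumours was 0.122 to 0.472 without 1 tumour, with an exact permutation p of 0.125 each, the smallest possible with 2 tumours left.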

Other observations

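Tests of peak calling, of list length, and of the calling window and missing sites of doxorubicin in tumour 6 were chosen only after the results were seen. The bounds of the other tests were set before their own values were computed, with the peak numbers and pairwise overlaps of the lists in part already known. Between pairs of EtOH lists, 5.53% to 40.3% of the peaks of one met a peak of the other. A shorter other list limits this share. The EtOH list of tumour 1, the shortest, met the longer lists of tumours 2, 3 and 4 with just 19.0%, 37.1% and 22.4% of its peaks. Within the OHT lists, peaks shared by all 4 tumours were wider than those of 1 tumour, with medians of 654 against 392 bp in tumour 3 and 466 against 425.5 bp in tumour 1. Doxorubicin in tumour 5 gave medians of 625 bp for peaks shared by its group and 391 bp for peaks not shared with another list of it.

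A hypothesis was that sites held by p53 in untreated Arf tumours are those that every restored tumour shares. Among regions of at least 1 OHT list, 35.4% of the 2605 with a peak in an untreated Arf list were in all 4 OHT lists, against 7.03% of the 10072 others. The ratio of 5.03 (Fisher's exact test over regions, which are not independent replicates, p = 4.48e-266) met the bound set beforehand. Within 4 classes of width, from narrowest to widest, the ratio was 5.86, 4.57, 3.17 and 2.02, each above the bound set beforehand. The narrowest class held just 53 of the 2605 regions and the widest 1711. In the narrowest class 1.89% of the 53 were in all 4 OHT lists, against 0.32% of 3104 others, so its ratio rests on very few regions. Part of the ratio thus goes with width. Width was not matched within a class, so its share in the rest stays open. Sites with high accessibility could give the same ratio, and accessibility was not analysed here.

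The OHT lists differed in length. Tumours 1 and 2 had 4102 and 3597 peaks, tumours 3 and 4 had 10084 and 9738, and a shorter list could be a part of the same set of sites. Of the peaks in tumour 1, 62.1% met a peak in both tumour 3 and tumour 4, and of those in tumour 2, 77.0%, values between the bounds set beforehand. Length alone stays open: of the 336 regions of untreated Arf tumours described in the results, the OHT list of tumour 1 held a share 43.5 percentage points above that of tumour 4 and 17.0 above that of tumour 3, and the list of tumour 2 differed by 19.9 from tumour 4 and by -6.55 from tumour 3, so that the shorter lists did not all differ from the longer ones in one direction. The rule was widened from the first of these pairs to all 4 after its value was seen. Of the 162 regions missing in tumour 4, 0% lay on chromosomes with over 90% missing. Among the 20 chromosomes with at least 5 of the 336 regions, the share missing ran from 14.3% to 76.9%. No chromosome thus lacked nearly all of its regions. Loss of a single copy need not remove every peak, so this test cannot decide on it. Narrower sites may be part of the cause, as the held region had the wider untreated peak in 70.8% of pairs, which lies between the bounds. Differences between tumours remain open and were not tested.

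The doxorubicin list of tumour 6 stood apart. Its mean Jaccard index with the other 5 doxorubicin and (-)-Nutlin lists was 0.335 against 0.434 for the next lowest list, and 21.3% of its regions were in no other list. Its smallest peak of 314 bp lay within the 278 to 391 bp of the others, which argues against another calling window, and without the regions found in 1 list the index was 0.38 against 0.453, so that these peaks are not the whole cause. Tumour 6 did not lack the sites, as 85.6% of the 3006 regions called with doxorubicin in tumours 5 and 7 but not 6 were called with (-)-Nutlin in tumour 6. Read depth, enrichment and a weaker response to doxorubicin in that sample remain open, and no biological explanation was tested.

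The change of peak width with treatment could affect the rise in peak numbers. In tumour 5, where every list was wide, the lower fold of activated over vehicle lists was 5.14, which argues against width as the cause there. For OHT, peaks within 500 bp of the next made up 11.4% to 39.6% of EtOH lists and 1.06% to 2.06% of OHT lists. Counting a site as several close peaks thus lowers the fold and could not produce the rise. Merging such peaks was bound to raise the fold, so it is no test of the rise. After it the lowest fold of the 4 tumours was 15.8 and the log2 ratio 4.76 instead of 4.48. A calling that finds fewer sites in the narrow EtOH lists, which merging does not correct, cannot be told apart from an effect of OHT, because 0 KI tumours had a pair of lists of the same kind.

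Control lists of tumour 5 held more peaks than those of tumour 7. They were wide where those of tumour 7 were narrow, so the kind of list cannot be told apart from the tumour. In each of the 4 conditions at least 97.1% of the tumour 5 peaks absent from the same control list of tumour 7 met a doxorubicin or (-)-Nutlin peak of tumour 7, above the bound set beforehand.

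Other splits of the libraries were counted for each set of regions that part the groups, gained and lost together. For OHT against EtOH 1 of 35 splits, the real one, reached 1191, and the highest other gave 79. This is a share under 0.05 only if libraries are taken as independent, although the tumours pair them. Within tumour pairs the highest other gave 6, but those 8 splits are too few for a share under 0.05. In the 6 against 12 comparison 1 of 100 splits drawn, the real one, reached 5935 calls and the highest other gave 0. Grouping by tumour also gave 0. Libraries of one tumour are not independent, so this count alone does not exclude chance. Every activated list held at least 5617 peaks and every other at most 2696, so the count largely restates the difference in list length. The 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real split gave 2728 for doxorubicin over water (highest other 173, and 55 among splits that part every pair), 3533 for (-)-Nutlin over DMSO (76 and 3) and 2989 over (+)-Nutlin (144 and 2), each reached by 1 split. For doxorubicin against (-)-Nutlin the real split gave 482 and 2 splits reached it, the highest with 1072. For (+)-Nutlin against DMSO it gave 1, which 9 of the 10 splits reached, the highest with 83.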
